A study of Bos taurus with 4 samples.

How the data were processed

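RNA from bovine intramuscular preadipocytes in 4 groups was measured on 12 bovine oligonucleotide arrays with 1 colour (Cy3), 3 arrays per group. Per the labels' protocols, 100 ng of total RNA, extracted with an organic solvent and treated with DNase, was amplified and labelled from a T7 primer carrying poly-dT. Each group is a single sample in the labels, with 3 array files, and the number of arrays (n = 3) stands for n throughout. The 12 arrays lay on 3 slides of 4. Slide 1 held the 3 day 0 arrays and day 6 control array 1, slide 2 held day 6 control arrays 2 and 3 and ATRA arrays 1 and 2, and slide 3 held ATRA array 3 and the 3 9cRA arrays. Slides and scans coincided.

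Each file holds the spot intensity on a linear scale, deposited by the authors as output of Feature Extraction 10.7.3.1. Per the file headers, background was subtracted with spatial and multiplicative detrending, and no normalization between arrays was applied. The authors also deposited a table of log2 values with 1 column per group. Set against the arrays, these are the mean over the group's 3 arrays of log2 signal minus the array's 75th percentile, centred on each probe's median. They cover 31205 probes, differed from values computed that way by medians of 0.00255 to 0.00276, and had column medians of 0.01 (day 0), -0.01 (day 6 control), 0.01 (ATRA) and 0.02 (9cRA). Correlations with the computed values were 0.992 (day 0), 0.967 (day 6 control), 0.935 (ATRA) and 0.949 (9cRA), so some probes differed by more than these medians. Scale, centring and direction were thereby settled from the values, and this table was used as an alternative.

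Each array held 45220 spots, of which 1417 were control spots and were left out. Of 525636 probe spots over all arrays, 191 were marked as outliers by the software and left out, and 0 were saturated. The signal at the 75th percentile lay between 1094 and 1359. The processed signal was taken to log2 and the array's 75th percentile subtracted. Spots of a probe were averaged, and a gene with several probes was represented by the probe with the highest mean. The number of arrays limits the precision. Of 43653 probes, 28356 were named through a RefSeq accession in a gene table of assembly ARS-UCD2.0 (used for names only), 5113 already carried a current symbol, 138 were named through an older symbol and 10046 kept the name in the file. Probe coordinates are those in the files, on UMD3.1. Probes of a gene were called with opposite signs for DES (ATRA and 9cRA against day 6 control), HOXB2 (day 6 control against day 0) and HSPB6 (ATRA against day 6 control). Probes of a gene also differed in size. Over culture the probe nearest 0 differed by 3.74 for A2M, 2.70 for ADGRB1, 3.17 for DGAT2, 1.00 for BNIP3, 8.16 for M-SAA3.2 and -0.97 for ENSBTAT00000057102. That of TF differed by 3.60 with ATRA and with 9cRA.

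A gene was tested if its probe was well above background on all 3 arrays of at least 1 group, which left 17598 genes, 12351 of them with a symbol. Means of the 4 groups were fitted over all 12 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, separately for each comparison. A gene not well above background on any array of a group has only a bound there. The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own. For 34 gene lists with at least 5 tested genes, camera was run with a preset correlation of 0.01 and adjusted over the lists of a comparison, and run again with an estimated correlation. The rotation test fry was an alternative. Adjusted p values of lists in the text are these.

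Genes were named by a rule. It takes the 8 largest increases and 8 largest decreases among called genes with a symbol that were well above background and unsaturated on all arrays of both groups and whose arrays did not overlap, which chance gives for 10% of genes with 3 arrays against 3. It adds the 3 largest bounds in each direction, up to 4 members with the smallest adjusted p of each list described, and always PPARG, CEBPA, FABP4, ADIPOQ, CYP26A1, CYP26B1, RARB and DHRS3. Some genes that the rule takes are not reported here. Genes outside the rule are said to be chosen after their values were seen. The groups, tests, lists, rule and most alternatives were chosen before the data were examined.

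The limma fit and camera with the preset correlation were tested on simulated data in which 200 of 17598 genes were changed by known folds. There 1 list, that of HOX genes, was shifted by 1 on the log2 scale, and it was called in every comparison. Recovery of smaller list shifts was not tested. Camera with an estimated correlation, fry and fits with slide as a block were not tested in this way. The simulated noise was independent between genes and held no slide effect. Of the lists not shifted, 1 was also called for 9cRA against day 6 control and 0 in the other comparisons. Overlaps between comparisons that share arrays were set beside 100 simulations in which all 12 arrays, shared controls included, were drawn with no gene changed. Medians of gene lists and probe sets were set beside 10000 random ones matched on signal, which do not keep correlation between members. Correlations used 1e+05 permutations. Alternatives were quantile and cyclic loess normalization, median scaling, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, outlier spots kept, fits on 2 groups only, an intensity trend with robust variance, the array number or the slide as a block, leaving out each array, a 2-fold limit, an adjusted p under 0.01, and the authors' deposited table. Slide as a random block, fits within a slide, and slide as a block for the gene lists, alone or with an estimated correlation, were added after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.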

Results

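Bovine intramuscular preadipocytes are fat cell precursors from the depot that lies within skeletal muscle. Their RNA was profiled on 1-colour oligonucleotide arrays at the start of adipogenic stimulation (day 0) and after 6 days in adipogenic medium. The medium held 10% fetal bovine serum, insulin (50 ng/mL), the glucocorticoid dexamethasone (0.25 µM) and the fatty acids acetate (10 mM, added as acetic acid) and octanoate (5 mM), and was changed every 2 days. Day 6 cultures received no retinoid (day 6 control), all-trans retinoic acid (ATRA) at 1 µM or 9-cis retinoic acid (9cRA) at 1 µM. Both compounds are acid forms of vitamin A and are stereoisomers that differ in the geometry at a single double bond. ATRA is known as a ligand of the retinoic acid receptors, and 9cRA as a ligand of these and of the retinoid X receptors. By its title, the series asks how vitamin A alters expression in these cells during adipogenesis.

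Each of the 4 groups was measured on 3 arrays, 12 arrays in all. The labels do not say whether the 3 arrays of a group held separate cultures, so the p-values measure only the spread between arrays, which may be technical. Between 64.8% and 74.0% of the probe spots on an array were well above background and no spot was saturated. The lowest share belonged to day 6 control array 1, which also carried 103 non-uniform spots against at most 2 on any other array. Median SDs of a gene between arrays were 0.06 (day 0), 0.12 (day 6 control), 0.08 (ATRA) and 0.09 (9cRA) on the log2 scale. Signals below are log2 relative to the array's 75th percentile, with the SD over n = 3 arrays, and differences are log2 with the SE and the adjusted p of limma over 17598 genes tested. Probe positions are those of the array's annotation on the UMD3.1 genome, which does not say whether a probe lies in an exon or an untranslated region.

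The first comparison, day 6 control against day 0, shows what differed after 6 days in adipogenic medium without added retinoid. No group was kept for 6 days outside that medium, so medium and time in culture cannot be told apart. FABP4, the fatty acid binding protein of fat cells (probe on chromosome 14, 46833756 to 46833815), went from 1.92 ± 0.03 to 6.26 ± 0.17, a 20.3-fold increase (adjusted p = 2.7e-10), and PPARG, the nuclear receptor that directs adipogenesis (chromosome 22, 57367139 to 57367198), went from -2.34 ± 0.07 to -0.52 ± 0.12, a 3.52-fold increase (adjusted p = 8.2e-09). Among genes well above background on all arrays of both groups the largest increase was that of SLC16A3, a lactate exporter (chromosome 19, 51243972 to 51244031), at 230.5-fold, from -5.73 ± 0.14 to 2.12 ± 0.10 (lowest log2 difference of its 4 probes 3.07). SAA3, a serum amyloid A gene well above background on 2 of 3 day 0 arrays, rose by 10.29 ± 0.22 on the log2 scale (lowest of its 6 probes 2.38). Genes of cholesterol synthesis, fatty acid synthesis, the cell cycle and the interferon response were lower at day 6, and so was the signal of probes for the forward strand of the mitochondrial genome. With an estimated correlation, adjusted p = 0.064 for the cholesterol list, adjusted p = 0.044 for fatty acid synthesis, adjusted p = 0.087 for the cell cycle and adjusted p = 0.053 for the interferon response.

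Of the other genes with the largest increases, ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 7.13 ± 0.08, PTX3, a secreted innate immune protein, by 7.13 ± 0.07 and RARRES1, a gene named for its response to retinoids, by 5.97 ± 0.07. SFRP1, a secreted Wnt antagonist, rose by 5.73 ± 0.14, ADGRB1 by 5.59 ± 0.15, TMEM59L by 5.38 ± 0.06 (lowest of its 4 probes 0.23) and MAOA, which oxidises monoamines, by 5.03 ± 0.11. Genes not well above background at day 0 have only a lower bound. M-SAA3.2, a serum amyloid A gene, was at least 712-fold higher at day 6, the chemokine CX3CL1 at least 127-fold and the protease inhibitor A2M at least 80.4-fold. Among the largest decreases were those of the chemokine CCL26 (-5.10 ± 0.14), the mitochondrial genes ND4 (-4.60 ± 0.09), ND4L (-4.57 ± 0.10) and ATP8 (-4.53 ± 0.11), the secreted protein gene ISLR (-4.33 ± 0.08), the homeobox gene LBX1 (-4.14 ± 0.13) and LGI2 (-4.12 ± 0.14). The apelin receptor gene APLNR was at least 42.5-fold lower, the transcript ENSBTAT00000057102 at least 26.3-fold and CLEC14A, a lectin gene of endothelium, at least 13.7-fold. CEBPA, the partner of PPARG in adipogenesis, differed by 0.13 ± 0.08 (adjusted p = 0.19), while its other probe differed by 1.36. DHRS3, a retinaldehyde reductase, differed by 0.03 ± 0.10 (adjusted p = 0.79). CYP26A1, which degrades retinoic acid, was at least 2.52-fold lower at day 6. CYP26B1 was not well above background in either group, ADIPOQ was not well above background on any array, and no probe carried the name RARB.

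**Figure D1:**
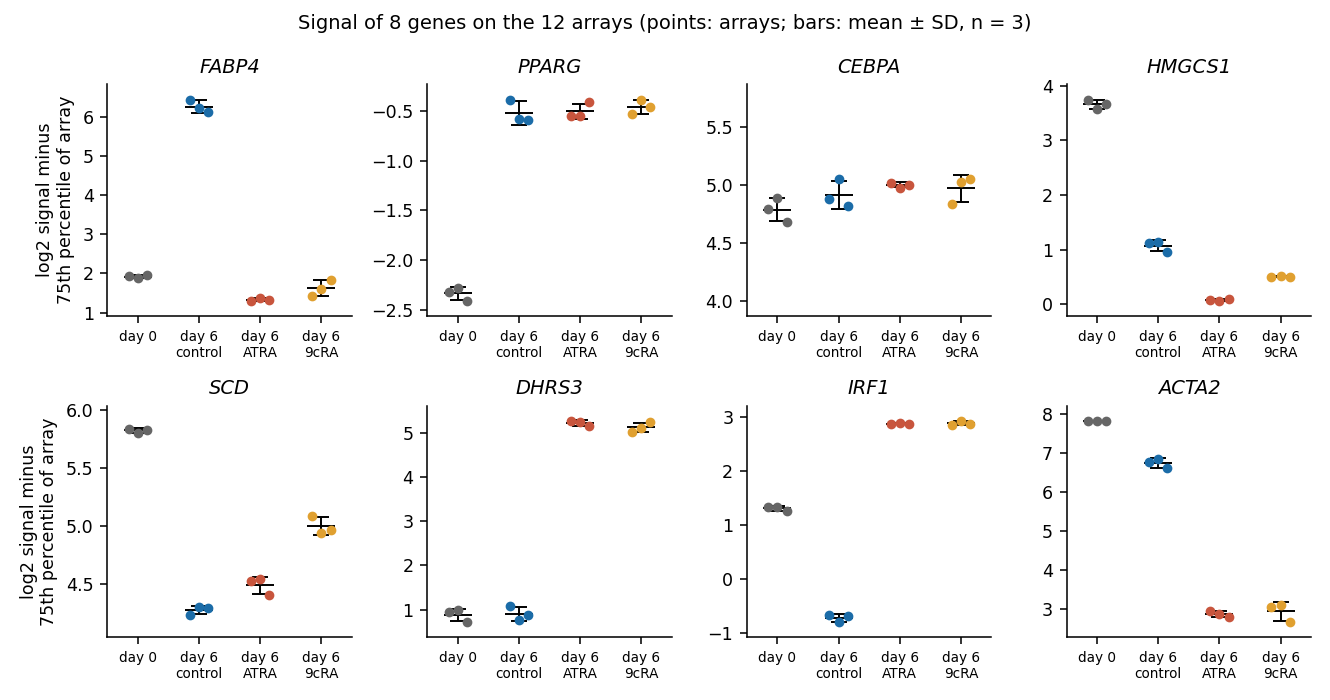
Log2 signal relative to the array's 75th percentile (y axis) of 8 genes in the 4 groups (x axis). Points are single arrays and bars are the mean and SD of 3 arrays. FABP4 lies near 1.92 at day 0, 6.26 in day 6 control, 1.33 with ATRA and 1.63 with 9cRA. PPARG lies near -0.52, -0.51 and -0.46 in the 3 day 6 groups.

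Among the gene lists fixed before the data were examined, those of glucocorticoid-induced genes, of glycolysis and hypoxia, and of Wnt signalling were higher at day 6. In this comparison, values with slide as a block rest on day 6 control array 1 alone, which carried 103 non-uniform spots. Of 25 glucocorticoid-induced genes, 18 rose, 3 fell and 4 were not called (18 and 3 adjusted over the list alone), with a median of 1.52 (1.48 with slide as a block). Examples are the anti-inflammatory regulator TSC22D3 (3.41 ± 0.06), MT2A, a metallothionein (4.41 ± 0.08, lowest of its 3 probes -0.39), and CRISPLD2 (3.07 ± 0.06). Its adjusted p was 7.7e-06 by camera and 0.044 with an estimated correlation. Of 34 glycolysis and hypoxia-induced genes, 29 rose, 0 fell and 5 were not called (30 and 0 adjusted over the list alone), with a median of 0.91 (1.00 with the block). They include the carbonic anhydrase CA9 (4.65 ± 0.07), ANKRD37 (4.74 ± 0.08) and BNIP3, a gene of mitophagy (3.16 ± 0.05), and the list had an adjusted p of 2.2e-12, and of 0.044 with an estimated correlation. Of 38 Wnt signalling genes, 20 rose, 7 fell and 11 were not called (20 and 7 adjusted over the list alone). The median was 0.34 (0.30 with the block, where the call was lost), with adjusted p = 0.034 by camera and adjusted p = 0.15 with an estimated correlation. The members with the smallest adjusted p were the antagonists SFRP1 and SFRP2 (1.40 ± 0.06) and the receptors FZD1 (1.48 ± 0.06) and FZD4 (1.13 ± 0.07). With an estimated correlation and slide as a block together, 0 lists were called in any comparison. The lists of glucocorticoid-induced genes, of glycolysis and of fatty acid synthesis were then at adjusted p = 0.17.

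Lipid synthesis genes fell. Of 25 genes of cholesterol synthesis and uptake, 1 rose, 22 fell and 2 were not called (1 and 22 adjusted over the list alone), with a median of -1.43 (-1.51 with the block). HMGCS1, which makes the precursor of mevalonate, changed by -2.59 ± 0.06, IDI1 by -2.38 ± 0.07 and INSIG1, a feedback regulator of sterol synthesis, by -2.12 ± 0.06. The list had an adjusted p of 1.2e-10 by camera and adjusted p = 0.064 with an estimated correlation. Of 20 genes of fatty acid synthesis and desaturation, 2 rose, 16 fell and 2 were not called (2 and 16 adjusted over the list alone), with a median of -0.97 (-0.94 with the block), adjusted p = 4.5e-05 by camera and adjusted p = 0.044 with an estimated correlation. The desaturases SCD (-1.55 ± 0.05) and FADS2 (-1.71 ± 0.06) fell while SCD5 rose (1.81 ± 0.04). The list of adipogenic transcription factors, with 20 genes, had 11 up, 4 down and 5 not called (11 and 4 adjusted over the list alone), a median of 0.30 (0.12 with the block) and an adjusted p of 0.059 by camera. ZBTB16 (4.02 ± 0.08), FOXO1 (2.35 ± 0.08) and CEBPD (1.52 ± 0.04) rose. The list of adipocyte lipid storage and secreted products, with 29 genes, had 11 up, 7 down and 11 not called (11 and 7 adjusted over the list alone) and a median of 0.13 (-0.10 with the block) at adjusted p = 0.41. Its risers included the lipid droplet protein PLIN2 (2.25 ± 0.05), the lipase LPL (2.49 ± 0.09) and DGAT2, of triglyceride synthesis, at least 12.1-fold higher.

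Cell cycle, interferon and respiratory chain genes were also lower. Of 49 cell cycle and DNA replication genes, 2 rose, 36 fell and 11 were not called (2 and 36 adjusted over the list alone), with a median of -0.51 (-0.54 with the block), adjusted p = 6.1e-06 by camera and adjusted p = 0.087 with an estimated correlation. The mitotic genes TPX2 (-1.28 ± 0.05), CDK1 (-1.52 ± 0.08) and KIF20A (-1.91 ± 0.13) fell and the replication helicase gene MCM7 rose (0.93 ± 0.05). Of 44 interferon-stimulated genes, 4 rose, 33 fell and 7 were not called (5 and 33 adjusted over the list alone), with a median of -0.86 (-0.92 with the block, -0.77 with dim genes at their bound), adjusted p = 1.7e-07 by camera and adjusted p = 0.053 with an estimated correlation. They include the transcription factor IRF1 (-2.03 ± 0.05) and the antiviral genes IFIT3 (-2.75 ± 0.07) and OAS1Y (-2.89 ± 0.09). Of 49 nuclear genes of oxidative phosphorylation, 0 rose, 37 fell and 12 were not called (0 and 37 adjusted over the list alone), with a median of -0.43 (-0.23 with the block), adjusted p = 4.8e-06 by camera and adjusted p = 0.54 with an estimated correlation. SDHA (-1.06 ± 0.07) and SDHB (-1.38 ± 0.11), subunits of succinate dehydrogenase, fell. Of 57 cytoplasmic ribosomal protein genes, 0 rose, 11 fell and 46 were not called (0 and 0 adjusted over the list alone), and the list's median of -0.14 turned to 0.03 with quantile or cyclic loess normalization. Its adjusted p of 0.030 by camera became adjusted p = 0.77 with an estimated correlation, and the call was lost with slide as a block (median -0.04) and without day 6 control array 3 (adjusted p = 0.27). Of 7 tendon and fibroblast markers, 0 rose, 5 fell and 2 were not called (0 and 5 adjusted over the list alone), with a median of -0.34 (-0.31 with the block, where the call was lost), adjusted p = 0.021 by camera and adjusted p = 0.13 with an estimated correlation. Among them were the early growth response gene EGR1 (-1.82 ± 0.10) and TNXB (-3.68 ± 0.11), a matrix protein gene that was well above background on 1 of the 3 day 6 control arrays.

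**Figure D2:**
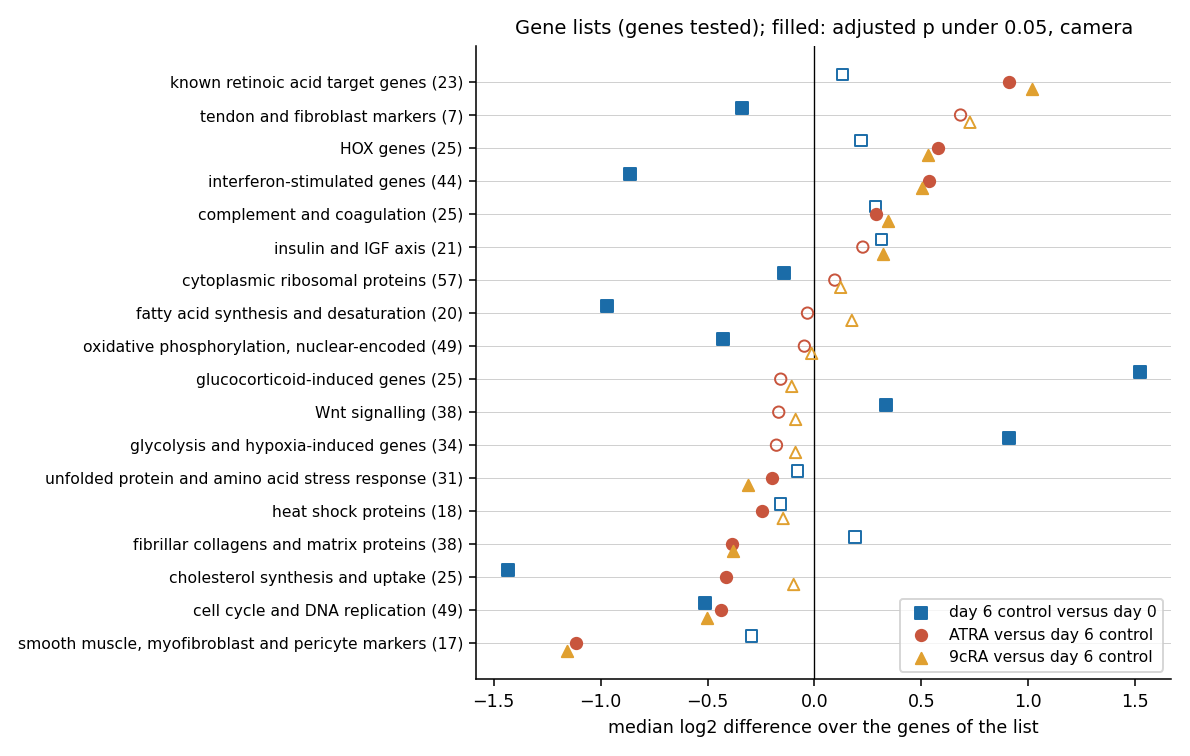
Median log2 difference (x axis) of 18 gene lists (y axis) in day 6 control minus day 0, ATRA minus day 6 control and 9cRA minus day 6 control. Filled symbols are lists called by camera with the preset correlation. Glucocorticoid-induced genes lie at 1.52 in the first comparison, and known retinoic acid targets at 0.91 and 1.02 in the retinoid comparisons.

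Probes for the mitochondrial genome moved apart by strand, a pattern chosen after its values were seen. All 36 probes for the forward strand, which carries most of the genes, fell, with a median of -3.07 (-2.999 within slide 1). Of 16 probes for the reverse strand, 12 rose, 0 fell and 4 were not called, with a fitted median of 1.98 (1.59 within slide 1). At day 0, 8 of these 16 probes, 7 of the risers among them, were not well above background on all arrays. With dim spots of both groups at their bound the median was 1.25, which is not a strict lower bound. Over the 8 reverse probes measured on all arrays of both groups, 5 rose, 0 fell and the median was 0.98. Medians of random sets of probes matched on signal ran from -0.40 to 0.12 for the forward set and from -0.71 to 0.99 for the reverse set. ND6, a protein gene of the reverse strand (position 13950 to 14009 of the mitochondrial genome), rose by 3.47 on the log2 scale, from -0.27 ± 0.18 to 3.201 ± 0.01, while ND4 (11328 to 11387) went from 5.48 ± 0.04 to 0.88 ± 0.20. ATRA raised 32 of the 36 forward probes (median 0.92) and 9cRA raised 30 (median 0.56). The retinoid groups still stood below day 0, at medians of -1.77 and -2.31.

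**Figure D3:**
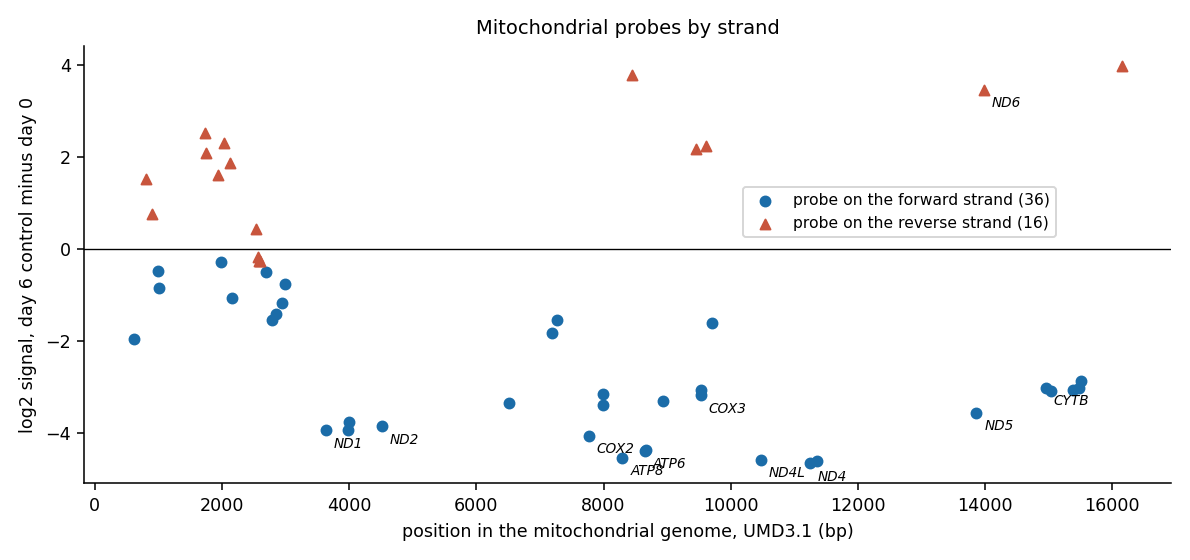
Log2 difference, day 6 control minus day 0 (y axis), against the position of each probe in the mitochondrial genome in bp (x axis). Circles are the 36 probes for the forward strand, with a median of -3.07, and triangles the 16 probes for the reverse strand, with a fitted median of 1.98, or 1.25 with dim spots of both groups at their bound.

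In all, 10966 of 17598 genes (62.3%) were called in this comparison, 5457 up and 5509 down, and 2510 of them changed at least 2-fold (1489 up and 1021 down). The split by direction depends on the scaling, and median scaling gave 4678 up and 6235 down. With slide as a block 9420 were called, 8527 of them shared with the first count in the same direction. Slide 1 alone, which held the 3 day 0 arrays and day 6 control array 1, gave 9616 calls. A single slide held both groups in each comparison that shares a slide, so the blocked estimates equal the within-slide ones. In data simulated with the spread of these arrays, 77.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 28 unchanged genes were called. Here and below, the simulation changed 200 genes and held no slide effect or correlation between genes. It cannot measure false calls that come from slide.

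The second comparison, ATRA against day 6 control, shows what all-trans retinoic acid changed within the same medium. FABP4 fell from 6.26 ± 0.17 to 1.33 ± 0.03, 30.6-fold lower (adjusted p = 3.7e-10) and below its day 0 level of 1.92 ± 0.03, while PPARG differed by 0.02 (95% interval -0.14 to 0.17) and CEBPA by 0.09 ± 0.08 (adjusted p = 0.40, other probe 0.22). DHRS3, which turns retinaldehyde back into retinol (chromosome 16, 42002077 to 42002136), rose from 0.91 to 5.23, 20.02-fold (adjusted p = 5.7e-10). Interferon-stimulated genes and HOX genes rose, and smooth muscle, collagen and cell cycle genes fell, by camera with the preset correlation. With an estimated correlation none of these lists was called, at adjusted p = 0.13 (interferon), adjusted p = 0.18 (HOX), adjusted p = 0.15 (smooth muscle), adjusted p = 0.29 (collagens and matrix) and adjusted p = 0.13 (cell cycle).

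Among genes well above background on all arrays of both groups, the largest increases were those of A2M (6.07 ± 0.17), TF, which encodes the iron carrier transferrin (6.02 ± 0.23), CLSTN3 (5.71 ± 0.18, its other probe 0.43), and CRABP1, a cytoplasmic retinoic acid binding protein (5.14 ± 0.13). They were followed by the monocarboxylate transporter SLC16A7 (4.93 ± 0.10), the metallothioneins MT1A (4.77 ± 0.09) and MT1E (4.60 ± 0.12), and MRAP, a melanocortin receptor accessory protein (4.56 ± 0.25). From not well above background in day 6 control, CRTAC1 was at least 46.1-fold higher, the transcription factor IRF8 at least 41.1-fold and LOC506828 at least 34.3-fold. DDC, which makes dopamine and serotonin from their precursors (chromosome 4, 5352560 to 5352619), fell most of these genes (-6.40 ± 0.09), from 3.08 ± 0.11 to -3.32 ± 0.10. Large decreases were also measured for PRG4, a joint lubricant protein (-4.63 ± 0.42), FNDC1 (-4.02 ± 0.14, its other probe 0.09), LMCD1 (-3.92 ± 0.10), the smooth muscle actins ACTA2 (-3.86 ± 0.11) and ACTG2 (-3.77 ± 0.09), and the matrix protein TNC (-3.60 ± 0.11). The transcript TC400954 was at least 14.3-fold lower, the channel gene CNGA3 at least 14.01-fold and PLXNB3 at least 6.92-fold. The retinoic acid hydroxylases CYP26A1 and CYP26B1 were at least 4.51-fold and at least 1.90-fold higher.

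Of 23 known retinoic acid target genes, 17 rose, 4 fell and 2 were not called (18 and 4 adjusted over the list alone), with a median of 0.91 (0.82 with slide as a block), adjusted p = 0.00018 by camera and adjusted p = 0.060 with an estimated correlation. Besides DHRS3 they include STRA6, a membrane transporter of retinol (5.27 ± 0.23, lowest of its 4 probes 0.26, well above background on 1 of 3 day 6 control arrays) and GPRC5A (2.41 ± 0.07). Of 25 HOX genes, 19 rose, 1 fell and 5 were not called (20 and 1 adjusted over the list alone), with a median of 0.58 (0.47 with the block), adjusted p = 3.6e-05 by camera and adjusted p = 0.18 with an estimated correlation. HOXB2 rose by 2.19 ± 0.08 (its other probe 0.24) and HOXB3 by 1.86 ± 0.10. Of 44 interferon-stimulated genes, 29 rose, 4 fell and 11 were not called (29 and 4 adjusted over the list alone), with a median of 0.54 (0.54 with the block), adjusted p = 2.9e-06 by camera and adjusted p = 0.13 with an estimated correlation. IRF1 rose by 3.59 ± 0.05, IFI27 by 3.23 ± 0.08 and the immunoproteasome gene PSMB8 by 2.74 ± 0.10. Of 25 complement and coagulation genes, 13 rose, 6 fell and 6 were not called (14 and 6 adjusted over the list alone), with a median of 0.29 (0.32 with the block), adjusted p = 0.010 by camera and adjusted p = 0.39 with an estimated correlation. C3 (2.87 ± 0.11) and C4A (3.08 ± 0.13) rose and the coagulation initiator F3 fell (-2.10 ± 0.07).

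Of 17 smooth muscle, myofibroblast and pericyte markers, 3 rose, 12 fell and 2 were not called (4 and 12 adjusted over the list alone), with a median of -1.11 (-1.12 with the block), adjusted p = 0.00015 by camera and adjusted p = 0.15 with an estimated correlation. Besides the actins, calponin (CNN1) fell (-1.58 ± 0.05). Of 38 fibrillar collagens and matrix proteins, 5 rose, 22 fell and 11 were not called (6 and 23 adjusted over the list alone), with a median of -0.39 (-0.41 with the block), adjusted p = 0.00024 by camera and adjusted p = 0.29 with an estimated correlation. LUM, a collagen-binding proteoglycan, fell (-2.75 ± 0.07), elastin (ELN) fell (-2.09 ± 0.07) and MGP, an inhibitor of calcification, rose (2.61 ± 0.07). Of 49 cell cycle genes, 2 rose, 29 fell and 18 were not called (3 and 31 adjusted over the list alone), with a median of -0.44 (-0.47 with the block), adjusted p = 2.9e-06 by camera and adjusted p = 0.13 with an estimated correlation. RRM2, of deoxynucleotide synthesis, fell by 2.34 on the log2 scale. Of 25 cholesterol genes, 4 rose, 17 fell and 4 were not called (4 and 18 adjusted over the list alone), with a median of -0.41 (-0.37 with the block), adjusted p = 8.6e-05 by camera and adjusted p = 0.29 with an estimated correlation. Of 31 genes of the unfolded protein and amino acid stress response, 3 rose, 16 fell and 12 were not called (3 and 17 adjusted over the list alone), with a median of -0.20 (-0.22 with the block), adjusted p = 0.00025 by camera and adjusted p = 0.39 with an estimated correlation. PSAT1, of serine synthesis, fell (-1.59 ± 0.08) and HERPUD1, of protein quality control in the endoplasmic reticulum, rose (2.66 ± 0.05). Of 18 heat shock protein genes, 1 rose, 9 fell and 8 were not called (1 and 9 adjusted over the list alone), with a median of -0.25 (-0.24 with the block), adjusted p = 0.010 by camera and adjusted p = 0.39 with an estimated correlation. With 9cRA, 3 of these rose, 8 fell and 7 were not called, with a median of -0.15 and adjusted p = 0.069 by camera.

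In all, 8116 genes were called with ATRA, 4174 up and 3942 down, of which 1379 changed at least 2-fold (744 up and 635 down). The majority turned with median scaling (3274 up and 4338 down), cyclic loess normalization (3973 and 4181), quantile normalization (4123 and 4130) and slide as a block (3317 and 3512). With slide as a block 6829 were called, 6322 of them shared in the same direction. Slide 2 alone, with 2 arrays of each group, gave 5276 calls. In simulated data, 65.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 34 unchanged genes were called.

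The third comparison, 9cRA against day 6 control, gave a picture close to that of ATRA in its leading genes. FABP4 fell 24.9-fold to 1.63 ± 0.21 (adjusted p = 6.5e-10), PPARG differed by 0.06 (95% interval -0.10 to 0.22), CEBPA by 0.06 ± 0.08 (adjusted p = 0.57, other probe 0.29), and DHRS3 rose 18.7-fold to 5.13 (adjusted p = 7.4e-10). With the same limit on background, the 8 largest increases were again A2M (6.14 ± 0.17), TF (6.06 ± 0.23), CLSTN3 (5.78 ± 0.18, its other probe 0.37), CRABP1 (5.14 ± 0.13), MT1A (4.81 ± 0.09), SLC16A7 (4.65 ± 0.10), MT1E (4.60 ± 0.12) and MRAP (4.48 ± 0.25). LOC506828, IRF8 and CRTAC1 were at least 37.8-fold, 35.3-fold and 34.6-fold higher. The 8 largest decreases with that limit were those of DDC (-6.29 ± 0.09), FABP4 (-4.64 ± 0.10), PRG4 (-4.34 ± 0.42), FNDC1 (-4.09 ± 0.14, its other probe -0.04), ACTA2 (-3.80 ± 0.11), TNC (-3.65 ± 0.11), ACTG2 (-3.61 ± 0.09) and LMCD1 (-3.59 ± 0.10). TC400954, CNGA3 and the serpin SERPINA11 were at least 12.8-fold, 12.5-fold and 6.21-fold lower. CYP26A1 was at least 4.02-fold higher, and CYP26B1 was called higher (adjusted p = 0.017). It was well above background on 2 of 3 9cRA arrays and on 0 day 6 control arrays, so no size is given. Its call was lost with slide as a block (adjusted p = 0.34, between 0.0034 and 0.34 over all alternatives), without day 6 control array 1 (0.057) and without 9cRA array 1 (0.062).

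With 9cRA, 9 lists were called. Of 23 retinoic acid targets, 18 rose, 4 fell and 1 was not called (18 and 4 adjusted over the list alone), with a median of 1.02 (0.94 with slide as a block), adjusted p = 0.00025 by camera and adjusted p = 0.067 with an estimated correlation. STRA6, not well above background on all day 6 control arrays, rose by 4.90 ± 0.23 (lowest of its 4 probes 0.31) and GPRC5A by 2.33 ± 0.07. Of 25 HOX genes, 18 rose, 1 fell and 6 were not called (18 and 1 adjusted over the list alone), with a median of 0.53 (0.46 with the block), adjusted p = 5.1e-05 by camera and adjusted p = 0.19 with an estimated correlation. Of 44 interferon-stimulated genes, 29 rose, 3 fell and 12 were not called (29 and 3 adjusted over the list alone), with a median of 0.50 (0.48 with the block), adjusted p = 3.9e-06 by camera and adjusted p = 0.11 with an estimated correlation, IRF1 at 3.60 ± 0.05. Of 25 complement and coagulation genes, 13 rose, 3 fell and 9 were not called (13 and 3 adjusted over the list alone), with a median of 0.34 (0.18 with the block), adjusted p = 0.0063 by camera and adjusted p = 0.36 with an estimated correlation. Of 21 genes of the insulin and IGF axis, 10 rose, 2 fell and 9 were not called (11 and 2 adjusted over the list alone), with a median of 0.32 (0.21 with the block), adjusted p = 0.021 by camera and adjusted p = 0.30 with an estimated correlation. It was led by the binding proteins IGFBP6 (2.35 ± 0.11) and IGFBP5 (2.30 ± 0.14) and the growth factor IGF2 (1.88 ± 0.10, lowest of its 12 probes -0.23). This call was also lost without 9cRA array 1 (adjusted p = 0.051). With ATRA the insulin and IGF list also had 10 genes up, 2 down and 9 not called. Its median there was 0.23, with adjusted p = 0.071 by camera. Of 17 smooth muscle markers, 3 rose, 11 fell and 3 were not called (4 and 12 adjusted over the list alone), with a median of -1.16 (-1.20 with the block), adjusted p = 0.00012 by camera and adjusted p = 0.14 with an estimated correlation, TAGLN at -3.004 ± 0.11. Of 38 matrix genes, 5 rose, 23 fell and 10 were not called (6 and 24 adjusted over the list alone), with a median of -0.38 (-0.46 with the block), adjusted p = 0.00011 by camera and adjusted p = 0.24 with an estimated correlation. Of 49 cell cycle genes, 3 rose, 30 fell and 16 were not called (3 and 32 adjusted over the list alone), with a median of -0.50 (-0.58 with the block), adjusted p = 1.2e-06 by camera and adjusted p = 0.11 with an estimated correlation. Of 31 stress response genes, 3 rose, 17 fell and 11 were not called (4 and 17 adjusted over the list alone), with a median of -0.31 (-0.28 with the block), adjusted p = 0.00026 by camera and adjusted p = 0.47 with an estimated correlation.

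In all, 8189 genes were called with 9cRA, 4356 up and 3833 down, of which 1394 changed at least 2-fold (772 up and 622 down). The majority turned with median scaling (3384 up and 4284 down) and cyclic loess normalization (4021 and 4146). No slide held both groups, and with slide as a block, where the difference rests on the ATRA arrays that share a slide with each, 4073 genes were called (1814 up and 2259 down), 3755 of them shared in the same direction and 1 in the opposite direction. In simulated data, 65.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and 46 unchanged genes were called.

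Set against day 0, the ATRA and 9cRA groups had 12582 and 12553 genes called. Both retinoids were compared with the same day 6 control arrays, and 6838 genes were called with both in the same direction (3467 up and 3371 down), against 3 called in opposite directions. Median scaling gave 2689 shared increases and 3733 shared decreases. Independent lists of these sizes would share 1033 increases and 859 decreases. Groups simulated with no gene changed, the control arrays drawn anew as well, shared 0.09 on average and at most 2. With no gene changed hardly any gene is called, so that count says little about an overlap of this size. The correlation of the log2 differences across genes, which are not independent replicates, was 0.962 against 0.676 in the simulation, and the covariance 0.436 against 0.0245, a difference of 0.411. The sign was the same for 89.3% of genes, against 73.6% in the simulation. With no gene changed, the simulated correlation and share of equal signs come from noise and the shared controls alone. They do not say how large either would be where many genes change. The simulation already holds the spread between the shared control arrays. It holds no slide effect and no difference common to the 3 control arrays, so part of the excess may still come from these. The 3 control arrays are too few to split into sets of 2.

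**Figure D4:**
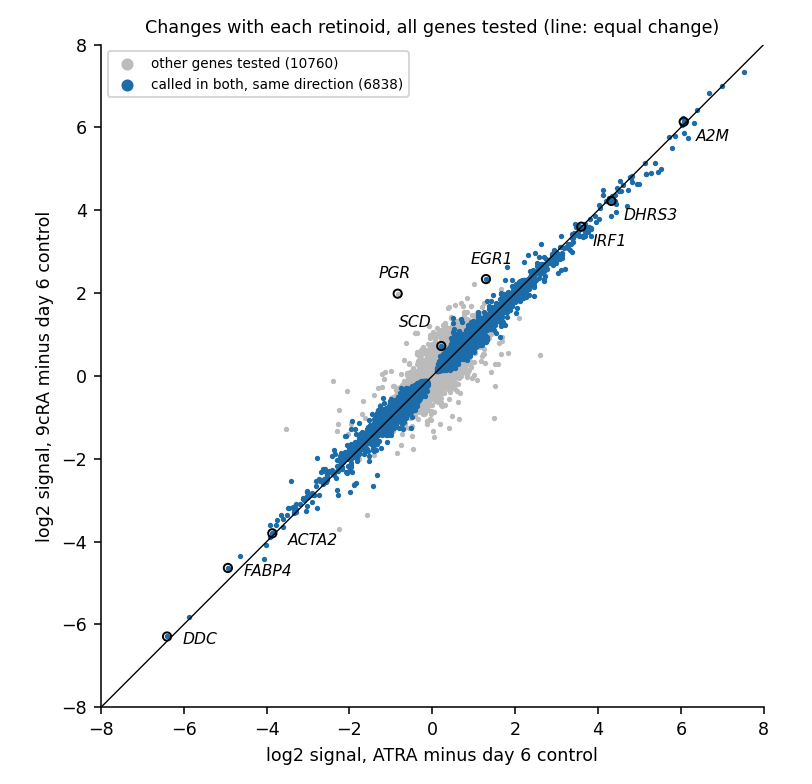
Log2 difference of 9cRA minus day 6 control (y axis) against ATRA minus day 6 control (x axis) for 17598 genes, with the line of equal change. Dark points are the 6838 genes called in both comparisons in the same direction. DDC lies at -6.40 and -6.29, A2M at 6.07 and 6.14, and EGR1 off the line at 1.29 and 2.34.

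The retinoid changes were also set against those of culture. Of the 10966 genes changed between day 0 and day 6 control, ATRA moved 2854 the opposite way (1524 of them up over culture and 1330 down) and 3014 the same way. Independent lists would share 2529 opposite changes and simulated unchanged groups, where hardly any gene is called, 0.03 on average. The correlation across genes was -0.06, against -0.75 in the simulation, and the covariance -0.0344 against -0.0245. With no gene changed, the simulated correlation, here and for 9cRA, comes from noise and the shared controls alone. It is no reference for the size of the real correlation. For 9cRA, 2927 genes moved the opposite way (1526 and 1401) and 2827 the same way, which is 26.7% and 25.8% of the genes changed over culture. Independent lists gave 2552 opposite changes, the correlation was -0.07 against -0.72, and the covariance -0.0401 against -0.0245. FABP4, IRF1 and CRABP1 were among the genes moved the opposite way, CRABP1 from 2.53 ± 0.05 at day 0 to 0.83 ± 0.32 in day 6 control and 5.97 ± 0.08 with ATRA. A2M, ANGPTL4 and MT1A were among those moved further in the same direction, MT1A from -1.76 ± 0.13 to 2.54 ± 0.19 and then to 7.31 ± 0.05 with ATRA and 7.36 ± 0.05 with 9cRA. Set against day 0, the median of interferon-stimulated genes was -0.32 with ATRA and -0.36 with 9cRA, that of cell cycle genes -0.92 and -1.06, and that of adipogenic transcription factors 0.31 and 0.32, against 0.30 in day 6 control. The medians of the transcription factors cover changes both ways. Against day 6 control, 4 of these 20 genes rose, 8 fell and 8 were not called with ATRA (adjusted p = 0.34 by camera). With 9cRA, 6 rose, 8 fell and 6 were not called (adjusted p = 0.44 by camera). Of 29 adipocyte lipid storage genes, 6 rose, 6 fell and 17 were not called with ATRA (adjusted p = 0.65 by camera). With 9cRA, 10 rose, 5 fell and 14 were not called (adjusted p = 0.48 by camera).

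The last comparison sets the stereoisomers against each other at the same dose and day. ATRA left the early growth response gene EGR1 2.06-fold lower than 9cRA did (-1.04, 95% interval -1.26 to -0.83, adjusted p = 0.012) and the desaturase SCD 1.42-fold lower (-0.51, interval -0.63 to -0.39, adjusted p = 0.012). The cholesterol genes HMGCS1 (-0.43, interval -0.56 to -0.30, adjusted p = 0.038), INSIG1 (-0.42, interval -0.55 to -0.30, adjusted p = 0.037) and NSDHL (-0.34, interval -0.46 to -0.23, adjusted p = 0.045) were also lower with ATRA. These 3 calls were lost with slide as a block, where the difference rests on 1 ATRA array and the SE was larger. HMGCS1 went from -0.43 ± 0.06 to -0.41 ± 0.09 (adjusted p = 0.13, between 0.010 and 0.36 over all alternatives). INSIG1 went from -0.42 ± 0.06 to -0.44 ± 0.08 (adjusted p = 0.095, between 0.0084 and 0.76) and NSDHL from -0.34 ± 0.05 to -0.38 ± 0.06 (adjusted p = 0.081, between 0.025 and 0.38). Without ATRA array 2, ATRA array 3 or 9cRA array 2, none of the 13 genes named by the rule for this comparison was called, EGR1 and SCD included. Not called were DHRS3, CRABP1, IRF1, DDC, CYP26A1 and FABP4, which both retinoids moved. DHRS3 differed by 0.10 (interval -0.12 to 0.32), CRABP1 by 0.00 (interval -0.30 to 0.30), IRF1 by -0.01 (interval -0.11 to 0.10), DDC by -0.11 (interval -0.32 to 0.10), CYP26A1 by 0.16 (interval -0.87 to 1.20) and FABP4 by -0.30 (interval -0.53 to -0.07, adjusted p = 0.35).

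Called genes also included FADS2 (-0.41), the immediate early gene IER2 (-0.46) and the progesterone receptor PGR, at least 1.54-fold lower with ATRA and not well above background there, on the side of lower signal with ATRA. On the other side were H2AC25, a histone gene (0.72), KRTCAP3 (0.70), the splicing factors RNPC3 (0.55) and LUC7L3 (0.45), and GUCY1B1, a subunit of guanylate cyclase (0.30). FCGR2B was called but not well above background in either group. Of 25 cholesterol genes, 0 were higher with ATRA, 3 lower and 22 not called (1 and 18 adjusted over the list alone), with a median of -0.28 (-0.31 with slide as a block), adjusted p = 1.3e-17 by camera and adjusted p = 0.049 with an estimated correlation. With the block and an estimated correlation together, adjusted p = 0.37 for this list and for fatty acid synthesis. Of 20 fatty acid synthesis genes, 0 were higher, 2 lower and 18 not called (0 and 3 adjusted over the list alone), with a median of -0.07 (-0.11 with the block), adjusted p = 0.00013 by camera and adjusted p = 0.049 with an estimated correlation. Of 34 glycolysis and hypoxia genes, 0 were called (0 and 0 adjusted over the list alone), with a median of -0.07 (-0.08 with the block), adjusted p = 0.013 by camera and adjusted p = 0.71 with an estimated correlation, and this call was also lost without ATRA array 2 (0.067), ATRA array 3 (0.13) or 9cRA array 1 (0.072). Relative to day 0, the cholesterol list stood at medians of -1.51, -1.38 and -1.54 on the day 6 control arrays, -2.09, -2.04 and -2.06 on the ATRA arrays, and -1.81, -1.86 and -1.73 on the 9cRA arrays. The distance between such medians is not the median of the gene differences. For 9cRA against day 6 control, 4 of the 25 genes rose, 9 fell and 12 were not called. The median there was -0.10 (-0.003 with the block), and the list was not called (adjusted p = 0.12 by camera).

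**Figure D5:**
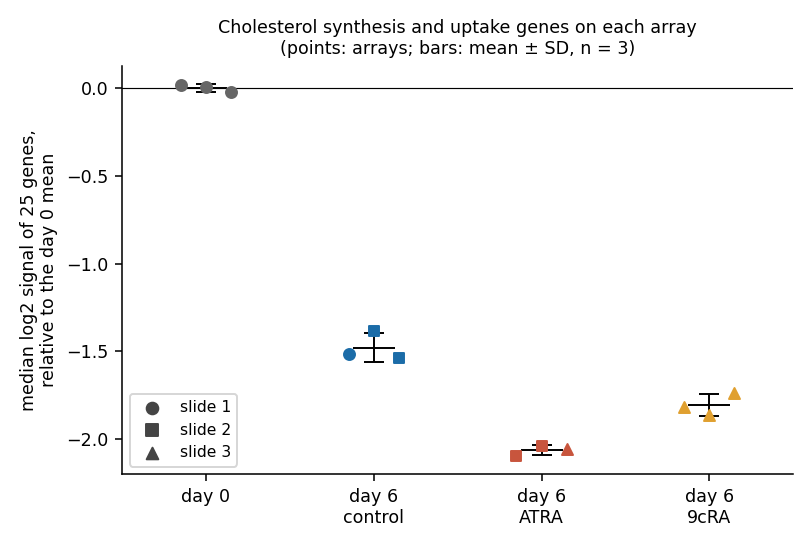
Median log2 signal of 25 genes of cholesterol synthesis and uptake on each array, relative to the day 0 mean (y axis), by group (x axis), with the marker showing the slide. The ATRA arrays lie between -2.09 and -2.04, the 9cRA arrays between -1.86 and -1.73, and the day 6 control arrays between -1.54 and -1.38. The distance between these medians is not the median of the gene differences between day 6 groups.

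Of 17598 genes, 21 were called between the isomers, 11 higher and 10 lower with ATRA, 4 of them at least 2-fold, and 1847 had an unadjusted p under 0.05. For 16658 genes (94.7%) the 95% interval of the difference lay within 2-fold either way, and simulated data gave back 65.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 92.4% of those changed 4-fold, with 5 unchanged genes called. The calls are sensitive to the arrays and to slide. Slide as a block gave 35 calls (30 up and 5 down), of which 4 were shared with the 21, EGR1 (adjusted p = 0.031, between 0.0012 and 0.24 over all alternatives) and SCD (adjusted p = 0.020, between 0.0028 and 0.33) among them. Of the 13 named calls, 11 were lost with the block. Slide 3 alone, with 1 ATRA array and 3 9cRA arrays, called 2 genes, 0 of them among the 21. Without 1 array the count lay between 0 and 27.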

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

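The difference between ATRA and 9cRA was planned as a test of its own, and the tests of slide for the cholesterol genes were chosen after the result was seen. For 21 of 17598 genes the effects of the stereoisomers differed by that test (limma, adjusted p under 0.05). Higher with ATRA were TC400636 (1.04), H2AC25 (0.72), KRTCAP3 (0.70), ENSBTAT00000009867 (0.69), A_73_106225 (0.61), RNPC3 (0.55), TC462897 (0.53), TC454367 (0.49), LUC7L3 (0.45), TC468452 (0.42) and GUCY1B1 (0.30), all on the log2 scale. Lower with ATRA were EGR1 (-1.04), AB098840 (-0.89), SCD (-0.51), IER2 (-0.46), HMGCS1 (-0.43), INSIG1 (-0.42), FADS2 (-0.41) and NSDHL (-0.34), with PGR at a fitted -2.82 (not well above background with ATRA, so only a bound holds) and FCGR2B at -1.24 (not well above background in either group). Unnamed transcripts and genes outside the named rule are listed because this test called them.

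Of these genes HMGCS1, INSIG1, NSDHL, SCD and FADS2 belong to lipid synthesis, and 23 of 25 genes of cholesterol synthesis and uptake had a lower mean with ATRA than with 9cRA, with a list median of -0.28. Scaling or background correction is argued against, since the median nearest to 0 over 5 other scalings and corrections was -0.26 and the largest camera adjusted p among them 5.6e-17. A single array is argued against as well, since without any 1 of the 12 arrays the median stayed between -0.31 and -0.26. Slide stays open, since with slide as a block, the same as within slide 3, the median was -0.31 and the difference between the arrays' list medians -0.26 (95% interval -0.43 to -0.09, with the spread taken from all 4 groups), but both rest on the 1 ATRA array on that slide and the list was not called with the block and an estimated correlation together (adjusted p = 0.37, between 6.6e-19 and 0.37 over all alternatives). The labels give 1 sample per group, so other differences between the cultures stay open too, and a difference between the isomers in sterol gene regulation may be the source only as a hypothesis.

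Among the 10 splits of the 6 arrays of 2 groups into 3 and 3, 1 split, the real one, gave the real count of calls in each comparison. Those real counts, in fits on the 2 groups alone, were 10393 (day 6 control against day 0), 6499 (ATRA against day 6 control), 6605 (9cRA against day 6 control) and 2 (ATRA against 9cRA), and the highest count of any other split was 0 in each. The share of splits is never under 0.1 here, so the splits are too few for a share under 0.05.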

How the results depend on the processing

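Slide as a random block, slide as a block for the gene lists and the fits within a slide were chosen after the results were seen, and all other alternatives before the data were examined. The direction of every named call was kept except where genes have several probes. Named genes that were not called were not checked for a change of direction. With the mean of a gene's probes, RPS14 turned to 0.88 and RPS15 to 0.32 (day 6 control against day 0), and DES to 1.33 (ATRA) and 1.48 (9cRA against day 6 control). For DES 2 of 3 probes were called with the opposite sign, and for the ribosomal genes the cause was not tested. With slide as a fixed block, 4 of 93, 0 of 88, 4 of 88 and 11 of 13 named calls were lost (culture, ATRA, 9cRA, ATRA against 9cRA).

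The count between ATRA and 9cRA, 21 genes, moved most. It was 32 with quantile normalization, 34 with normexp, 60 with normexp and quantile, 5 without the filter on dim probes, 40 with the filter on all 12 arrays, 2 with only the 2 groups, 61 with an intensity trend and robust variance, 35 with slide as a fixed block, 5 as a random block, 2 within slide 3, 4 at 2-fold and 0 at an adjusted p under 0.01 in limma (1847 at an unadjusted p under 0.05). The share of higher calls, 52.4%, became 63.3% with cyclic loess, 66.7% with normexp and quantile, and 85.7% with the block. Leaving out 1 array gave 0 to 27, with 7, 7 and 8 without day 0 arrays 1, 2 and 3, 6 without day 6 control array 2, 10, 1 and 0 without ATRA arrays 1, 2 and 3, and 0 without 9cRA array 2. Array numbers gave no sign of paired samples, which 3 arrays per group spread over slides cannot exclude. Arrays sharing a number had deviations correlated between -0.199 and 0.104, 3 of 12 arrays correlated best with their own number, and with the replicate block 2 genes were called.

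With median scaling the share of higher calls fell from 49.8% to 42.9% (culture), 51.4% to 43.0% (ATRA), 53.2% to 44.1% (9cRA) and 50.7% to 41.9% (both). With slide as a fixed block, 4073 genes were called for 9cRA (44.5% higher, against 53.2%), 3827 with both retinoids in the same direction, and 1548 moved by 9cRA against culture. At 2-fold the counts were 2510 (culture), 1379 (ATRA), 1394 (9cRA), 1191 (both), 360 and 346 (against culture, ATRA and 9cRA), fewer by construction, as were 1950 for 9cRA against culture at an adjusted p under 0.01 and 5276 for ATRA within slide 2, with fewer arrays. Leaving out 1 array gave 10001 to 11565 (culture), 6908 to 8173 (ATRA), 6676 to 8353 (9cRA), 6026 to 6932 (both), 2527 to 2956 and 2424 to 3041 (against culture). Without day 6 control array 1 the counts were 11565, 7602, 7711 and 27.

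Lists called by camera, 10, 10, 9 and 3, became 3, 0, 0 and 2 with an estimated correlation, 29, 24, 25 and 2 with fry, which tests no difference from other genes, and 0 in each comparison with slide as a fixed block and an estimated correlation together. Leaving out 1 array gave 9 to 11, 10 to 13, 9 to 11 and 2 to 6, the last without 9cRA array 1. Wnt signalling and tendon markers lost their call with quantile normalization and with slide as a block, and ribosomal proteins with both, with fry and without day 6 control array 3 (adjusted p = 0.27 by camera). Glycolysis genes between the isomers lost it with fry and without ATRA array 2 (0.067), ATRA array 3 (0.13) or 9cRA array 1 (0.072), and the insulin and IGF axis without 9cRA array 1 (0.051). For all changes not said to follow from construction, the cause was not tested. Signal over background limits genes near the floor, since only 64.8% to 74.0% of probe spots on an array were well above background.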

Other observations

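The tests on HOX paralogues, on immediate early genes, on array quality, on a swapped label and on dim mitochondrial probes were chosen after the results were seen, and the tests on scaling, RNA integrity and day 0 RNA before. Some lists of markers of other cell types were not called. Of 13 endothelial markers, 6 rose, 1 fell and 6 were not called with ATRA (8 and 1 adjusted over the list alone), with a median of 0.44 (0.22 with slide as a block) at a camera adjusted p of 0.091, and 6 rose, 1 fell and 6 were not called with 9cRA (7 and 1 adjusted over the list alone), with a median of 0.45 (0.03 with the block) at an adjusted p of 0.14. VWF, a clotting factor carrier of endothelium, rose by 2.34 ± 0.11 and 1.96 ± 0.11, and EMCN, a sialomucin of endothelium, was at least 11.6-fold and 13.05-fold higher. Of 14 macrophage and leukocyte markers, 6 rose, 2 fell and 6 were not called with ATRA (6 and 2 adjusted over the list alone), with a median of 0.28 (0.13 with the block) at an adjusted p of 0.11. CD14, a receptor for bacterial lipopolysaccharide, rose by 1.89 ± 0.09 over culture (lowest of its 3 probes 0.38) and by 2.31 ± 0.09 with ATRA (lowest 0.84). Of 17 osteogenic and chondrogenic markers, 6 rose, 2 fell and 9 were not called with ATRA (6 and 2 adjusted over the list alone), with a median of 0.23 (0.05 with the block) at an adjusted p of 0.20, while SPP1, the bone matrix protein osteopontin, rose by 4.19 ± 0.08 with ATRA and 4.21 ± 0.08 with 9cRA. Of 20 skeletal muscle markers, 4 rose, 7 fell and 9 were not called over culture (4 and 7 adjusted over the list alone), with a median of 0.02 (-0.11 with the block) at an adjusted p of 0.53. MB, the oxygen carrier myoglobin, changed by -2.92 ± 0.09 (its other probe -1.11).

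Metallothioneins and neighbours of FABP4 were looked at after their values were seen. MT2A rose by 4.41 ± 0.08 over culture and by 4.27 ± 0.08 with ATRA and 4.30 ± 0.08 with 9cRA, and MT1E rose by 1.08 ± 0.12, 4.60 ± 0.12 and 4.60 ± 0.12. FABP5, a fatty acid carrier of the same family as FABP4 on chromosome 14, rose by 0.69 ± 0.10 over culture and changed by -1.99 ± 0.10 with ATRA and -1.81 ± 0.10 with 9cRA. FABP9, well above background only in day 6 control, was at least 2.37-fold higher there than at day 0. SCD and FASN, which fell over culture, rose with both retinoids, SCD by 0.22 ± 0.05 with ATRA and 0.72 ± 0.05 with 9cRA, and FASN by 0.72 ± 0.09 and 0.97 ± 0.09. The list of 20 fatty acid synthesis genes was called with neither retinoid. With ATRA, 7 rose, 7 fell and 6 were not called, with a median of -0.03 (0.01 with the block, adjusted p = 0.86 by camera). With 9cRA, 10 rose, 4 fell and 6 were not called, with a median of 0.17 (0.04 with the block, adjusted p = 0.44 by camera). Inflammatory genes went both ways with ATRA, 13 up, 11 down and 10 not called of 34 (13 and 11 adjusted over the list alone), with a median of 0.16 (-0.01 with the block) at an adjusted p of 0.94, among them the leukocyte adhesion molecule VCAM1 (2.62 ± 0.09) and the chemokines CXCL12 (2.41 ± 0.11) and CCL5 (-2.90 ± 0.11).

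The strands of the mitochondrial genome moved apart between day 0 and day 6, by a fitted 5.05 on the log2 scale. The gap was 4.32 with dim spots of both groups at their bound, and 4.05 over the probes measured on all arrays of both groups. Scaling is argued against, since the gap was 4.78 with quantile and 4.87 with cyclic loess normalization, and 4.03 and 4.17 with dim spots at their bound. A loss of RNA integrity at day 6 is argued against as the whole cause, since over 5651 nuclear genes with probes apart the 3' probe changed by a median of 0.0822 more than the 5' probe (0.11 over the 2508 genes with closer probes). In 7 mitochondrial genes that median was 0.90, from 0.06 in ND4 to 1.80 in COX1, and labelling started from poly-dT. A change in mitochondrial RNA abundance or in its polyadenylation may lie behind the pattern, and neither was tested.

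Day 6 control array 1 stood apart from the other day 6 control arrays. Its spike-in spots had an SD of 0.137 on the log2 scale against 0.0426 to 0.0766 on the other 11 arrays, which is consistent with lower array quality. A label swapped with day 0 is argued against, since on a scale from 0 at day 0 to 1 at the other 2 day 6 control arrays the array lay at 0.889 across genes. Some day 0 RNA in its sample stays open, since the slope of its deviation on the day 0 minus retinoid difference was 0.0686, between the limits set for either answer. No biological explanation was tested.

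Of 25 HOX genes, those with low paralogue numbers may respond more to ATRA, a hypothesis from these data. Spearman's rho of paralogue number and log2 difference was -0.51 (permutation p = 0.0106) and Pearson's r was -0.496 (permutation p = 0.0113), or -0.362 without the 2 genes farthest from the median. The 10 genes with numbers up to 5 had a median of 0.94 and the 15 others 0.46, and rho was -0.41 with 9cRA. These correlations are across genes, which are not independent replicates.

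EGR1 and IER2 were called lower with ATRA than with 9cRA, and FOS differed by -0.77 (adjusted p = 0.079). Other immediate early genes may share that difference. Over 17 of them the median was -0.12 and 15 had a lower mean with ATRA, a median at percentile 0 of 10000 matched random lists, though 0 of these 17 genes passed the test over all genes. The random lists were matched on signal only and do not allow for a correlation between immediate early genes. The percentile therefore cannot decide whether they share the difference. With slide as a block, where the difference rests on 1 ATRA array, the median was -0.14 and 12 of the 17 were lower. EGR1 was still called there (adjusted p = 0.031, between 0.0012 and 0.24 over all alternatives) and IER2 was not (adjusted p = 0.14, between 0.011 and 0.47), at -0.44 ± 0.10 against -0.46 ± 0.07 without the block.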
